A study of Homo sapiens with 16 samples.

How the data were processed

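RNA sequencing was done on HEK293 cells, a line derived from human embryonic kidney, that overexpressed GFP, wild-type RNF43 or 1 of 2 RNF43 frameshift variants, R117fs and G659fs. Each of the 4 groups had 4 libraries, 16 in all, and the labels gave each library its group and its replicate number. Per the labels' protocols, total RNA was extracted with RNeasy columns and DNase I and libraries were made with NEBNext reagents for Illumina. Whether RNA was selected for poly(A), the read length, the strand setting and whether the replicates came from separate cultures were not given in the sources used here. The p-values therefore measure the spread between these samples, which may be technical.

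Per the submitters' processing notes, transcripts were quantified with kallisto 0.45.1 on GRCh38. The annotation release behind the transcripts and the run options were not given in the sources used here. The deposited files gave, for each of 178136 transcripts, an estimated count of reads, which is not a whole number, and a TPM value, which per the file headers is scaled by effective length. The estimated counts summed to between 20364357 and 46779570 per library, which sets the precision of every count below. In the deposited files the effective length of transcripts over 1000 bases was the length minus 199 bases. The deposited TPM values were used for the transcripts of RNF43 and PGK1 alone.

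Transcripts were matched by identifier to GENCODE 29, an annotation of GRCh38 that may not be the submitters' own. Of the 178136 transcripts 162453 (91.2%) matched, 89.55% with the same version. The 15683 that did not match held 1.904% to 2.216% of the counts of a library and were left out. The estimated counts of the matched transcripts were summed per gene over 35075 genes and rounded to whole numbers. Of 28028 genes with counts, 16787 passed the low-count filter (filterByExpr) and were tested. Reads shared between near-identical genes are divided by estimation, so values of pseudogenes and close paralogs are uncertain, and overlapping or antisense genes cannot be told apart without a strand setting. Coordinates are those of GENCODE 29 on GRCh38.

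Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, robust dispersion estimates, the quasi-likelihood fit (glmQLFit, robust, in its newer form) and glmQLFTest, in 1 fit of all 16 libraries with 1 coefficient per group, so that all groups share 1 estimate of the spread. The plan had been to run the newer form without a dispersion step, but the installed version needs dispersions, so they were estimated first. P-values were adjusted by the Benjamini-Hochberg method over the 16787 genes of a comparison, and a gene counted as changed at an adjusted p under 0.05. Where adjusted p is given below without another tool's name it comes from this edgeR test for a gene and from camera for a gene list. Fold changes are on the log2 scale with standard errors, taken from the fold change and the F value of the test. These errors rest on the shared spread. They may be too small for R117fs, whose libraries differed more among themselves than those of the other groups. CPM is counts scaled to a total of 1000000 per library after TMM and is given as mean ± SD of 4 libraries. The common biological coefficient of variation was 0.103, and the first 2 principal components held 19.8% and 18.4% of the variance. The closest of the 24 pairs of libraries within a group differed by a chi-square per degree of freedom of 3.55 (3.13 without RNF43), so no library was taken for a duplicate of another in its group. Pairs across groups were not compared in this way.

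Before the data were examined, 23 gene lists were fixed, along with the tests, the groups and the rule for naming genes. They covered Wnt/beta-catenin targets, Wnt ligands and receptors, TNF/NF-kappaB responses, RAS/MAPK output, immediate early genes, hypoxia, the unfolded protein response, the integrated stress response, cholesterol synthesis, type I interferon responses, p53 targets, DNA replication, mitosis, heat shock, proteasome subunits, TGF-beta and BMP targets, YAP/TAZ targets, glycolysis, mitochondrially encoded proteins (a sign of RNA quality), replication-dependent histones (a sign of RNA selection) and markers of haematopoietic cells, gut epithelium and fibroblasts. RNF43 was in no list. The hypoxia and glycolysis lists shared 6 genes and the 2 Wnt lists 2. Wnt/beta-catenin targets shared 1 gene with RAS/MAPK output and 1 with YAP/TAZ targets. The integrated stress response shared 1 with immediate early genes and 1 with hypoxia. TGF-beta and BMP targets shared 1 with fibroblast markers. Lists were tested with camera (limma 3.58.1), which compares a list with all other genes, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 23 lists of a comparison. With a correlation estimated from the data, which also lowers the degrees of freedom of the test, 4 of the calls held, namely p53 targets in the 3 comparisons with GFP and the unfolded protein response in R117fs against GFP. The estimates ran from -0.044 for gut epithelial markers to 0.585 for mitochondrially encoded proteins. They were 0.051 for p53 targets, 0.086 for TNF/NF-kappaB responses and 0.4 for the unfolded protein response, against the preset 0.01. For each list the members past the threshold were counted with p adjusted over all genes and also adjusted over the list alone.

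The rule for named genes took RNF43 and, among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between 4 and 4 libraries, the 8 largest rises and 8 largest falls (4 and 4 for G659fs against R117fs), and up to 4 members of each list with the smallest adjusted p. From these, genes of unclear identity were left out, and genes whose call was lost under an alternative are named with that value or left out. Some genes that the rule took are not reported.

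The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 of 16787 genes changed, 50 for each fold. For WT against GFP, the edgeR test recovered 7 of 50 genes changed 1.25-fold, 35 changed 1.5-fold, 47 changed 2-fold and 49 changed 4-fold, with 10 false calls. For G659fs against WT it recovered 9, 36, 49 and 50 with 4 false calls. Over the 6 comparisons, 7 to 15 of the 50 genes changed 1.25-fold were recovered, and folds between 1.25 and 1.5 were not simulated. With the unfolded protein response list raised 1.5-fold, camera at its preset correlation called it in every comparison. It also called 1 unchanged list in R117fs against GFP. Genes were drawn independently, with the same dispersion in all groups and no GC trend, so false calls may be more frequent in the real data.

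Comparisons with GFP share their 4 control libraries. The correlation of their fold changes is therefore given beside that of 20 simulations of unchanged groups against the same controls, the overlap of independent lists, and the value with the GFP libraries split 2 and 2. The alternatives tried were RLE size factors, removal of RNF43 counts before normalization, no low-count filter, a filter of CPM of at least 1 in at least 4 libraries, effective transcript length as an offset, the legacy quasi-likelihood fit, DESeq2 1.42.0, limma-voom, a fit of the 8 libraries of a comparison, the replicate number as a block, an estimated correlation and the rotation test fry for lists, and each library left out in turn. The test fry asks whether a list moved at all, and camera whether it moved more than other genes, so a difference between them does not by itself contradict a call. Removing each library's trend with GC content (medians of 20 bins) was added after the data were seen. The intervals given for single libraries are exact Clopper-Pearson intervals and cover counting error only. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.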

Results

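Gene expression was measured by RNA sequencing in HEK293 cells, a human line derived from embryonic kidney, that overexpressed GFP, wild-type RNF43 (WT) or the RNF43 frameshift variants R117fs and G659fs. RNF43 is a transmembrane E3 ubiquitin ligase that removes Frizzled receptors from the cell surface and so dampens Wnt signalling. By its title, the series asked how far expression profiles tell what a gene variant does. Each of the 4 groups had 4 libraries. Total estimated counts were 25441077 to 30937321 in the GFP libraries, 32761360 to 46779570 in WT, 20364357 to 41161835 in R117fs and 29886062 to 44738520 in G659fs. R117fs replicate 4 was farthest from its group: the SD of its genes' deviations from the other libraries of its group was 0.4845 on the log2 scale, against at most 0.2679 in the other 15 libraries, and across genes these deviations followed GC content (Spearman 0.883, over genes, which are not independent replicates). R117fs replicate 1 also lay apart by its counts, with a chi-square per degree of freedom of 72.41, 81.91 and 83.18 against replicates 2, 3 and 4, where replicates 2 and 3 differed by 5.62. Without RNF43 these were 17.13, 16.44, 54.35 and 3.86, while replicate 4 differed from replicates 2 and 3 by 62.46 and 49.97. Results are given with all 16 libraries, and values without R117fs replicate 4 stand beside the counts it moved.

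The overexpressed gene was checked first. RNF43 (ENSG00000108375; GRCh38 chromosome 17, 58352500 to 58417595, minus strand) was at 31.4 ± 15.4 CPM in GFP cells (SD, n = 4), 53350 ± 8058 in WT, 68440 ± 27520 in R117fs and 39390 ± 5415 in G659fs. Against GFP this was a rise of 1701-fold in WT, 2183-fold in R117fs and 1256-fold in G659fs (edgeR adjusted p = 8.5e-08, 4.7e-08 and 9.9e-08), and all 12 RNF43 libraries lay above all 4 GFP libraries. The constructs did not differ from each other past the threshold: the log2 difference was 0.36 ± 0.35 for R117fs against WT (edgeR adjusted p = 0.543), -0.44 ± 0.35 for G659fs against WT (0.499) and -0.80 ± 0.35 for G659fs against R117fs (0.144). With the effective length offset the first turned to -0.29 (edgeR adjusted p = 0.69), so its direction depends on that setting. The offset takes annotated lengths, and most R117fs counts lay on a transcript of 4367 bases, longer than the coding sequence of 2352 bases. That length may therefore not hold for the construct. Without R117fs replicate 1 the difference of G659fs against R117fs became -1.05 with an edgeR adjusted p of 0.0276. Read counts also depend on the length of the RNA, which was not settled for R117fs. Similar counts therefore do not show similar numbers of RNA molecules. RNF43 counts were divided between annotated transcripts differently by construct. The protein-coding transcript ENST00000577625 held 72.5% ± 0.42 of RNF43 counts in WT and 71.9% ± 0.25 in G659fs but 0.0032% ± 0.0014 in R117fs, where ENST00000577716 held 99.4% ± 0.36 (SD, n = 4 each).

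**Figure D1:**
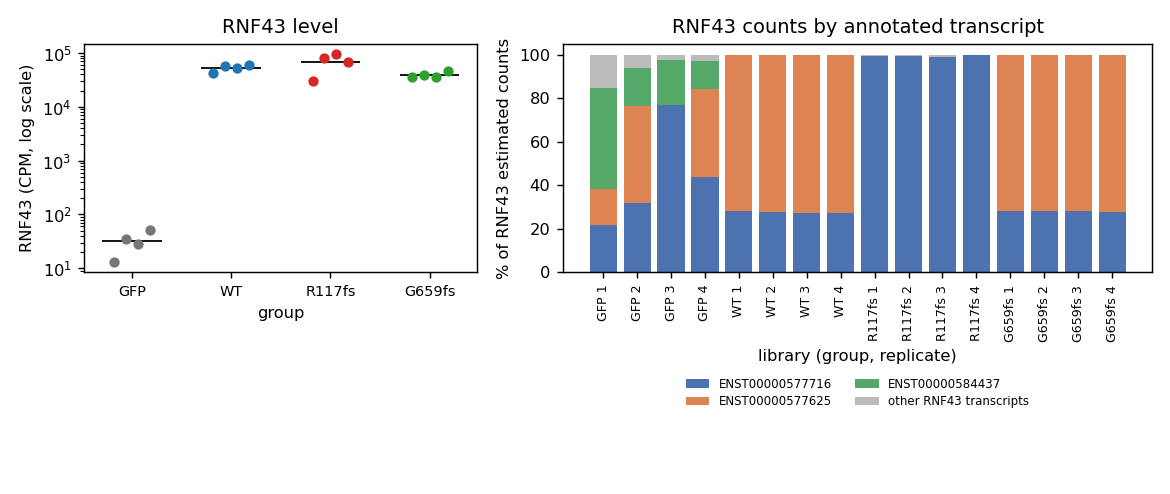
RNF43 in the 16 libraries. Left, CPM per library by group on a log axis, with the group mean as a horizontal line: the 12 RNF43 libraries lie far above the 4 GFP libraries. Right, the percent of RNF43 counts on each annotated transcript, stacked per library: ENST00000577625 holds most counts in WT and G659fs and next to none in R117fs.

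Wild-type RNF43 was compared with GFP to see what the overexpressed ligase changed. EGR1, an immediate early transcription factor induced by growth factor signalling (ENSG00000120738; chromosome 5, 138465490 to 138469315), rose 5.42-fold, from 7.98 ± 1.60 to 43.2 ± 13.2 CPM (SD, n = 4). The inflammatory cytokine genes CXCL8 and IL32 rose 14.4-fold and 4.72-fold, the extracellular matrix gene TNC 3.06-fold and the inducible cyclooxygenase gene PTGS2 2.93-fold. CXCL8 was near the floor in GFP (0.28 ± 0.12 CPM, against 3.92 ± 1.43 in WT), so the size of its rise is uncertain. FTCD, an enzyme of histidine breakdown (ENSG00000160282; chromosome 21, 46136262 to 46155567), fell by 2.38 ± 0.12 on the log2 scale, from 7.87 ± 0.55 to 1.51 ± 0.06 CPM, and ALPK3, an alpha kinase, fell by 1.79 ± 0.14. HSPA6, a heat-inducible chaperone, rose 21.4-fold (39.1 ± 23.9 against 1.83 ± 0.09 CPM), a value that is uncertain because the gene is nearly identical to HSPA7. ESRP1, an epithelial splicing factor, rose 3.43-fold, and CFAP43, a ciliary protein, SMC1B, a meiotic cohesin subunit, and INPP5D, a lipid phosphatase of blood cells, fell by 1.62 ± 0.13, 1.76 ± 0.22 and 1.59 ± 0.15. Their edgeR adjusted p ran from 1.7e-09 for FTCD to 0.000298 for HSPA6. In all, 3603 of 16787 genes changed (21.46%), 1654 higher and 1949 lower, and 349 changed at least 2-fold, 96 higher and 253 lower. The count was 2222 without GFP replicate 4, 6133 without R117fs replicate 4, and 5919 in a fit of the 8 libraries alone. Higher calls outnumbered lower ones without R117fs replicate 4 (3109 and 3024) and with the GC trend removed (6074 in all, 3046 and 3028).

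Stress and inflammatory lists rose with wild-type RNF43 by camera at its preset correlation, and none passed with an estimated correlation. Of 20 tested unfolded protein response genes, which restore folding in the endoplasmic reticulum, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with camera adjusted p = 1.3e-08 and adjusted p = 0.227 with an estimated correlation. XBP1 was at 0.56 ± 0.07, DNAJB9 at 0.79 ± 0.11 and MANF at 0.82 ± 0.13 on the log2 scale. Of 21 integrated stress response genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone), among them ATF3 (0.77 ± 0.07) and the serine and asparagine enzymes ASNS (0.44 ± 0.08), MTHFD2 (0.46 ± 0.09) and SHMT2 (0.37 ± 0.07), with camera adjusted p = 5.8e-07 and adjusted p = 0.284 with an estimated correlation. Among 22 TNF/NF-kappaB response genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone), led by IL32 (2.24 ± 0.20), CXCL8 (3.85 ± 0.37), the inhibitor NFKBIA (0.51 ± 0.09) and TNFAIP3 (0.79 ± 0.15), with camera adjusted p = 5.0e-05 and adjusted p = 0.148 with an estimated correlation. Immediate early genes rose in 7 of 23 cases, with 0 falling (8 and 0 adjusted over the list alone), including EGR1 (2.44 ± 0.20), KLF4 (0.53 ± 0.09) and ARC (0.84 ± 0.19); camera gave adjusted p = 0.00572, 0.0529 without WT replicate 2, and adjusted p = 0.552 with an estimated correlation.

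Metabolic lists also rose in WT at the preset correlation. Of 18 glycolysis genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone), with camera adjusted p = 0.00062 and adjusted p = 0.375 with an estimated correlation. PFKP rose by 0.42 ± 0.07 and HK2 by 0.35 ± 0.06, while ENO2 fell by 0.61 ± 0.07. PGK1 (chromosome X, 77910739 to 78129296) was the other that fell, by 0.87 ± 0.06, but with effective transcript length as an offset its log2 fold change was 1.48 in the opposite direction, so its sign depends on that setting. Of 22 cholesterol synthesis genes 6 rose and 0 fell (7 and 1 adjusted over the list alone), NSDHL by 0.26 ± 0.06 (camera adjusted p = 0.00949; adjusted p = 0.438 with an estimated correlation). For the proteasome, 4 of 27 subunit genes rose and 0 fell (0 and 0 adjusted over the list alone), and none of the 4 calls held under every alternative (camera adjusted p = 0.00062; adjusted p = 0.227 with an estimated correlation). Mitochondrially encoded protein genes, which follow RNA quality, rose in 3 of 13 cases with 0 falling (3 and 0 adjusted over the list alone); camera adjusted p was 0.0064, 0.0522 without WT replicate 1, 0.0734 with the GC trend removed and 0.0664 by fry, and adjusted p = 0.552 with an estimated correlation.

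The p53 targets, which restrain the cell cycle or promote apoptosis, were the list that fell in WT: 0 of 18 rose and 10 fell (0 and 11 adjusted over the list alone). BTG2 fell by 1.14 ± 0.10, FDXR by 0.72 ± 0.08, SPATA18 by 0.68 ± 0.08 and PHLDA3 by 0.89 ± 0.12 on the log2 scale (camera adjusted p = 5.8e-07, and 0.0256 with an estimated correlation). Wnt/beta-catenin targets did not move as a list: 2 of 17 rose, MYC (0.49 ± 0.10) among them, and 1 fell (1 and 0 adjusted over the list alone), with camera adjusted p = 0.635. Of 28 Wnt ligands and receptors 1 rose and 1 fell (0 and 0 adjusted over the list alone; camera 0.245). For the remaining lists, given as risen and fallen of those tested, camera did not pass: RAS/MAPK output 4 and 0 of 20 (adjusted p = 0.0921), hypoxia 6 and 4 of 25 (0.679), type I interferon 6 and 1 of 18 (0.0708), DNA replication 3 and 1 of 20 (0.195), mitosis 2 and 0 of 20 (0.333) and heat shock 1 and 2 of 16 (0.795). TGF-beta and BMP targets had 4 and 1 of 17 (0.126), YAP/TAZ targets 4 and 0 of 16 (0.245), histones 3 and 1 of 10 (0.338), haematopoietic markers 0 and 2 of 9 (0.288), gut epithelial markers 1 and 0 of 6 (0.858) and fibroblast markers 2 and 1 of 8 (0.858). Adjusted over the list alone these pairs were 4 and 0, 7 and 5, 7 and 3, 4 and 1, 1 and 0, 2 and 2, 4 and 1, 4 and 0, 3 and 1, 0 and 2, 1 and 1, and 2 and 1. Leaving out 1 library gave 3 of these lists a call: RAS/MAPK without GFP replicate 2 (0.0246), GFP replicate 4 (0.0342) or WT replicate 1 (0.00118), interferon without GFP replicate 2 (0.0298), GFP replicate 4 (0.0421) or WT replicate 4 (0.0446), and TGF-beta and BMP without WT replicate 1 (0.0165). Tested by fry against no change, interferon genes gave 0.00438 and YAP/TAZ genes 0.0214.

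R117fs was compared with GFP next. Genes of the endoplasmic reticulum were among the largest rises: HSPA5, the main chaperone of this compartment (ENSG00000044574; chromosome 9, 125234853 to 125241330), went from 630.2 ± 24.8 to 2119 ± 612.5 CPM (3.36-fold; SD, n = 4), the disulfide isomerase PDIA4 from 184.5 ± 9.97 to 706 ± 202 CPM (3.82-fold), and DERL3, which acts in the degradation of misfolded proteins, from 1.57 ± 0.35 to 13.0 ± 4.0 CPM (8.12-fold). SDF2L1 rose 3.27-fold, MANF 2.89-fold and the chaperone HYOU1 2.64-fold. SLC22A31, a predicted transporter, rose 8.40-fold. ALPK3 fell by 3.29 ± 0.17, the reductase gene DHRS2 by 2.65 ± 0.28, FTCD by 2.54 ± 0.13, TCEAL7 by 2.24 ± 0.20, GPNMB by 2.23 ± 0.18 and the dynein gene DNAH17 by 2.15 ± 0.12 on the log2 scale. Their edgeR adjusted p ran from 1.4e-09 for ALPK3 and FTCD to 2.9e-05 for DHRS2. In all 2620 genes changed (15.61%), 1182 higher and 1438 lower, and 213 at least 2-fold, 48 higher and 165 lower. The count was 1718 without GFP replicate 2 and 1455 without GFP replicate 4, 1740 with the effective length offset, 588 with the 8 libraries alone and 4433 with the GC trend removed; without R117fs replicate 4 it was 3701. Higher calls outnumbered lower ones without R117fs replicate 1 (1447 and 1419).

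The unfolded protein response had the smallest camera p of the 23 lists, with 19 of 20 genes risen and 0 fallen (19 and 0 adjusted over the list alone) and a median log2 fold change of 0.71 (camera adjusted p = 1.5e-21, and 0.0365 with an estimated correlation). HSPA5 rose by 1.75 ± 0.14, PDIA4 by 1.94 ± 0.15 and HYOU1 by 1.40 ± 0.11. The integrated stress response had 6 of 21 genes risen and 0 fallen (10 and 0 adjusted over the list alone), ATF3 by 0.47 ± 0.07 (camera adjusted p = 0.00074; adjusted p = 0.594 with an estimated correlation; 0.0663 by fry). Cholesterol synthesis genes rose in 3 of 22 cases and fell in 0 (6 and 0 adjusted over the list alone), DHCR7 by 0.48 ± 0.10 (camera adjusted p = 0.00074; adjusted p = 0.42 with an estimated correlation). Glycolysis had 6 of 18 risen and 2 fallen, ENO2 by 0.44 ± 0.07 (8 and 2 adjusted over the list alone); camera adjusted p was 0.0103, 0.242 by fry, and adjusted p = 0.594 with an estimated correlation. The other that fell was PGK1, at -1.10 ± 0.06, which turned to 1.18 with the effective length offset. Mitochondrially encoded genes had 1 of 13 risen and 0 fallen (0 and 0 adjusted over the list alone), camera adjusted p = 0.0182 and adjusted p = 0.73 with an estimated correlation. That call was lost without GFP replicate 2 (0.0596), GFP replicate 3 (0.0912), R117fs replicate 3 (0.0535) or R117fs replicate 4 (0.0582), and fry gave 0.159.

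Heat shock, mitosis and p53 genes fell in R117fs at the preset correlation. Of 16 heat shock genes 0 rose and 7 fell (0 and 11 adjusted over the list alone), with camera adjusted p = 1.1e-05 and adjusted p = 0.313 with an estimated correlation. Among chaperone genes HSPH1 was at -0.88 ± 0.10, DNAJB1 at -1.05 ± 0.12 and HSP90AA1 at -0.67 ± 0.11. Of 20 mitosis genes 0 rose and 9 fell (0 and 14 adjusted over the list alone), such as the spindle checkpoint kinase BUB1 (-0.58 ± 0.12) and the motor KIF11 (-0.48 ± 0.12), whose edgeR adjusted p became 0.0531 and 0.104 with the 8 libraries alone (camera adjusted p = 4.3e-06; adjusted p = 0.489 with an estimated correlation). Targets of p53 fell in 11 of 18 cases and rose in 0 (12 and 0 adjusted over the list alone), among them BTG2 (-0.99 ± 0.10), TP53INP1 (-0.94 ± 0.13), FDXR (-0.56 ± 0.09) and the cell cycle inhibitor CDKN1A (-0.58 ± 0.09), with camera adjusted p = 8.3e-07 and 0.0256 with an estimated correlation. RAS/MAPK output genes fell in 5 of 20 cases and rose in 0 (6 and 1 adjusted over the list alone), the transcription factor ETV5 by 1.84 ± 0.34 (edgeR adjusted p = 0.00171, and 0.102 with the effective length offset). The camera adjusted p of that list was 0.0291, with adjusted p = 0.73 with an estimated correlation, and it was lost without GFP replicate 2 (0.0906), GFP replicate 4 (0.052), R117fs replicate 1 (0.293) or R117fs replicate 4 (0.0648) and with the GC trend removed (0.0512), and fry gave 0.149. The other 14 lists did not pass, with camera adjusted p from 0.171 to 0.993; of these, histones passed without R117fs replicate 1 (0.0414), and fry gave hypoxia 0.0264. Wnt/beta-catenin targets had 1 of 17 risen and 0 fallen (1 and 0 adjusted over the list alone), with camera adjusted p = 0.993.

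G659fs was then set against GFP. EGR1 rose 7.15-fold to 57.0 ± 4.5 CPM, CXCL8 24.1-fold, the immediate early factor FOS 4.53-fold, IL32 4.42-fold, ZCCHC12 4.41-fold, and ETV5, a factor induced by RAS/MAPK signalling (ENSG00000244405; chromosome 3, 186046308 to 186110318), 3.54-fold to 8.74 ± 1.00 CPM against 2.48 ± 0.90 (SD, n = 4). CXCL8 was at 6.62 ± 1.28 CPM in G659fs against 0.28 ± 0.12 in GFP, which is near the floor. DHRS2 fell by 2.94 ± 0.28, INPP5D by 2.57 ± 0.17, FTCD by 2.44 ± 0.12, the ciliary genes CFAP43 and WDR78 by 2.31 ± 0.14 and 2.04 ± 0.15, and the adhesion gene NECTIN4 by 1.91 ± 0.14 on the log2 scale. Their edgeR adjusted p ran from 1.3e-09 for FTCD to 0.000644 for FOS. This comparison changed 4258 genes (25.36%), 1946 higher and 2312 lower, and 422 at least 2-fold, 103 higher and 319 lower. The count was 6723 without R117fs replicate 4, 6556 with the GC trend removed and 6993 with the 8 libraries alone, of which 3558 were higher and 3435 lower.

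**Figure D2:**
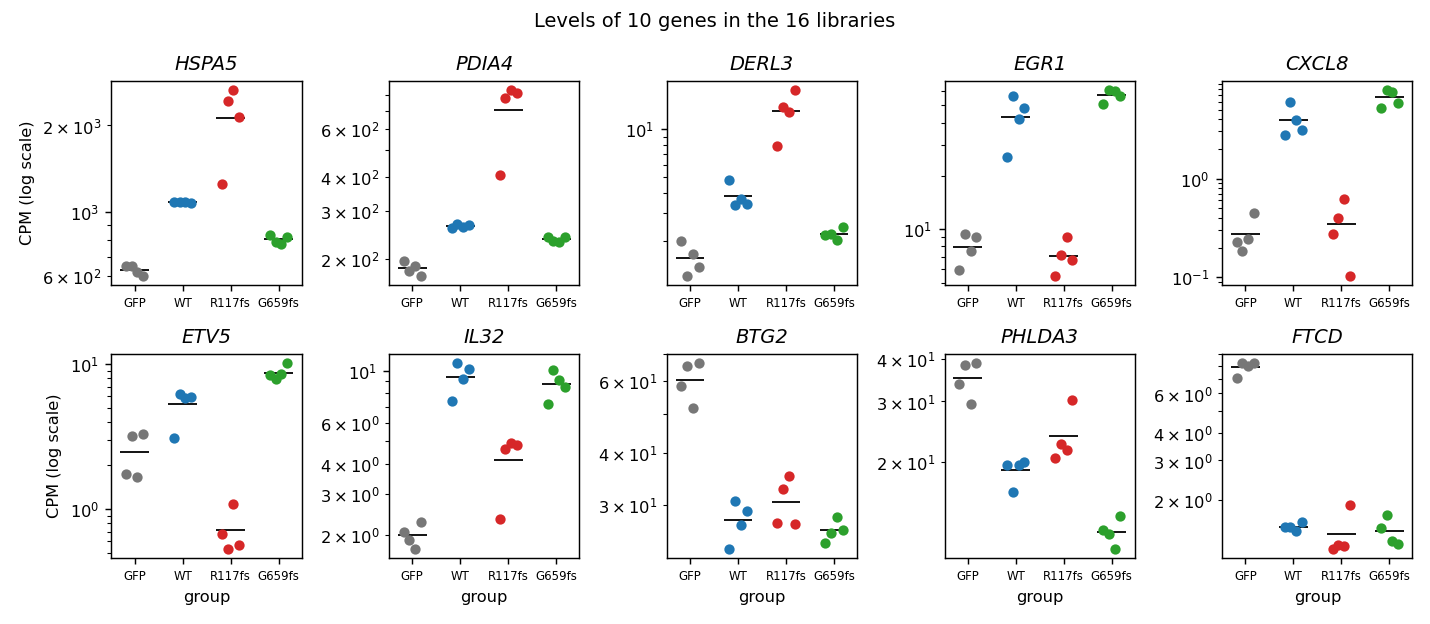
CPM of 10 genes in the 16 libraries on a log axis, by group, with the group mean as a line. HSPA5, PDIA4 and DERL3 are highest in R117fs, EGR1, CXCL8 and ETV5 are higher in WT and G659fs than in R117fs, and BTG2, PHLDA3 and FTCD are highest in GFP.

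Signalling lists rose in G659fs at the preset correlation. Of 23 immediate early genes 11 rose and 0 fell (15 and 0 adjusted over the list alone), with camera adjusted p = 3.5e-07 and adjusted p = 0.238 with an estimated correlation. EGR1 was at 2.84 ± 0.20, ARC at 1.28 ± 0.19, KLF4 at 0.63 ± 0.09 and EGR3 at 1.82 ± 0.31. RAS/MAPK output rose in 11 of 20 genes and fell in 0 (13 and 1 adjusted over the list alone), with camera adjusted p = 4.1e-05 and adjusted p = 0.346 with an estimated correlation. The feedback inhibitor SPRY4 was at 2.50 ± 0.27, ETV5 at 1.82 ± 0.22 and ETV4 at 1.41 ± 0.26. TNF/NF-kappaB genes rose in 13 of 22 cases and fell in 0 (13 and 1 adjusted over the list alone), with camera adjusted p = 2.5e-06 and adjusted p = 0.0663 with an estimated correlation. CXCL8 rose by 4.59 ± 0.34, NFKBIA by 0.95 ± 0.09 and TNFAIP3 by 0.97 ± 0.15. For TGF-beta and BMP targets, 9 of 17 rose and 1 fell (12 and 2 adjusted over the list alone), with camera adjusted p = 9.1e-05 and adjusted p = 0.168 with an estimated correlation. They included FN1 (0.56 ± 0.08), ID2 (0.53 ± 0.07), SMAD6 (0.64 ± 0.10) and ID3 (0.49 ± 0.08). Of 28 Wnt ligands and receptors 8 rose and 0 fell (8 and 0 adjusted over the list alone), with camera adjusted p = 0.00341 and adjusted p = 0.136 with an estimated correlation. The Frizzled receptor genes FZD9 rose by 0.70 ± 0.10, FZD8 by 0.55 ± 0.10, FZD7 by 0.30 ± 0.07 and FZD1 by 0.38 ± 0.08.

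Of 17 Wnt/beta-catenin targets 6 rose and 1 fell in G659fs (7 and 2 adjusted over the list alone). MYC rose by 0.56 ± 0.10, CCND1 by 0.74 ± 0.15 and the secreted Wnt inhibitor DKK1 by 1.14 ± 0.22, and AMOTL2 fell by 0.41 ± 0.09; MYC and CCND1 also answer growth factor signalling. Camera gave the list adjusted p = 0.0466 and adjusted p = 0.396 with an estimated correlation, and the call was lost without GFP replicate 1 (0.0564), GFP replicate 3 (0.127), R117fs replicate 4 (0.102) or G659fs replicate 3 (0.0617) and with the GC trend removed (0.16). YAP/TAZ targets rose in 5 of 16 cases and fell in 2 (5 and 2 adjusted over the list alone), CYR61 by 0.58 ± 0.09, ANKRD1 by 1.03 ± 0.19 and CTGF by 0.51 ± 0.10. Their camera adjusted p was 0.033, with adjusted p = 0.168 with an estimated correlation, 0.0695 without GFP replicate 1, 0.0534 without R117fs replicate 4 and 0.079 with the GC trend removed.

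In G659fs 8 of 20 unfolded protein response genes rose and 0 fell (13 and 1 adjusted over the list alone), PDIA6 by 0.32 ± 0.07 and MANF by 0.44 ± 0.13 (camera adjusted p = 0.000667; adjusted p = 0.375 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 22 cases and fell in 1 (14 and 1 adjusted over the list alone), with camera adjusted p = 9.1e-05 and adjusted p = 0.17 with an estimated correlation. HSD17B7 was the member that fell, and it fell by 0.45 ± 0.08. Glycolysis genes rose in 11 of 18 cases and fell in 2 (13 and 2 adjusted over the list alone), with camera adjusted p = 0.00163 and adjusted p = 0.346 with an estimated correlation. PGAM1 rose by 0.33 ± 0.06 and TPI1 by 0.38 ± 0.07. ENO2 fell by 0.36 ± 0.07 and PGK1 by 0.84 ± 0.06, which became 1.49 in the opposite direction with the effective length offset. Mitochondrially encoded genes rose in 7 of 13 cases and fell in 0 (10 and 0 adjusted over the list alone), MT-ATP8 by 0.41 ± 0.08 (camera adjusted p = 9.1e-05; adjusted p = 0.346 with an estimated correlation). Integrated stress response genes rose in 7 of 21 cases and fell in 1 (7 and 2 adjusted over the list alone), ATF3 by 0.41 ± 0.07 (camera adjusted p = 0.0497; adjusted p = 0.665 with an estimated correlation). That call was lost without GFP replicate 2 (0.115), GFP replicate 4 (0.246), WT replicate 1 (0.0566), WT replicate 2 (0.0602), WT replicate 3 (0.0509), G659fs replicate 1 (0.163) or G659fs replicate 4 (0.0524) and with the replicate block (0.0582), and fry gave 0.15.

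The list that fell in G659fs was also p53 targets, with 15 of 18 fallen and 0 risen (16 and 0 adjusted over the list alone). The falls of this list in WT, R117fs and G659fs were all measured against the same GFP libraries and are not independent repeats. A difference of the GFP cells themselves would lower the list in every construct, and this was not tested. PHLDA3 fell by 1.49 ± 0.12, BTG2 by 1.22 ± 0.10, SPATA18 by 1.07 ± 0.09 and FDXR by 0.92 ± 0.09 (camera adjusted p = 1.7e-10, and 0.00359 with an estimated correlation). The other 10 lists did not pass, with camera adjusted p from 0.2 to 0.957, and fry gave interferon genes 0.0162 and fibroblast markers 0.0486. Of 8 fibroblast markers 2 rose and 1 fell (2 and 1 adjusted over the list alone), LUM by 0.98 ± 0.22.

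R117fs was compared with WT directly. TCEAL7 fell by 2.97 ± 0.19 on the log2 scale, from 7.27 ± 1.45 CPM in WT to 0.983 ± 0.254 in R117fs (SD, n = 4), EGR1 by 2.64 ± 0.21 (43.2 ± 13.2 to 7.08 ± 1.48 CPM) and DNAH17 by 2.03 ± 0.12. CXCL8 fell by 3.52 ± 0.35, ETV5 by 2.94 ± 0.30 and SPRY4 by 2.96 ± 0.36. In R117fs CXCL8 and SPRY4 were near the floor, at 0.35 ± 0.22 and 0.18 ± 0.05 CPM. SLC22A31 rose 4.37-fold, DERL3 3.34-fold, RUNDC3A 2.68-fold, PDIA4 2.67-fold and LGALS9 2.33-fold. Their edgeR adjusted p ran from 2.5e-08 for DNAH17 to 0.0012 for LGALS9. In this comparison 1362 genes changed (8.113%), 755 higher and 607 lower, and 175 at least 2-fold, 77 higher and 98 lower. Without WT replicates 1, 2, 3 and 4 in turn the count was 779, 626, 696 and 660, and without R117fs replicate 1 it was 2607. It was 853 with the effective length offset and 154 with the 8 libraries alone, and 1617 without R117fs replicate 4. The balance turned to 801 higher and 816 lower without that library, and to 1310 and 1556 (2866 in all) with the GC trend removed.

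Unfolded protein response genes were higher in R117fs than in WT, 13 of 20 risen and 0 fallen (14 and 1 adjusted over the list alone), PDIA4 by 1.42 ± 0.15, HSPA5 by 0.97 ± 0.14, HYOU1 by 0.84 ± 0.11 and CRELD2 by 0.69 ± 0.10 (camera adjusted p = 6.6e-08; adjusted p = 0.195 with an estimated correlation). The mean log2 CPM of the list was 7.362 in R117fs replicate 1, close to WT (7.241 to 7.283), and 7.706 to 7.823 in the other 3 R117fs libraries. Mitosis genes were lower, with 9 of 20 fallen and 0 risen (18 and 0 adjusted over the list alone), with camera adjusted p = 1.7e-09 and adjusted p = 0.194 with an estimated correlation. UBE2C fell by 0.36 ± 0.05. Heat shock genes fell in 9 of 16 cases and rose in 0 (11 and 0 adjusted over the list alone), with camera adjusted p = 9.2e-08 and adjusted p = 0.194 with an estimated correlation. DNAJB1 fell by 0.81 ± 0.12, HSPA8 by 0.79 ± 0.12 and HSP90AA1 by 0.62 ± 0.11. TNF/NF-kappaB genes fell in 10 of 22 cases and rose in 1 (12 and 2 adjusted over the list alone), with camera adjusted p = 1.8e-05 and adjusted p = 0.194 with an estimated correlation. IL32 fell by 1.22 ± 0.18 and the chemokine CCL20 by 2.90 ± 0.61. RAS/MAPK output fell in 7 of 20 genes and rose in 0 (10 and 0 adjusted over the list alone), ETV5 and SPRY4 among them (camera adjusted p = 1.9e-05; adjusted p = 0.404 with an estimated correlation). For DNA replication 6 of 20 fell and 0 rose (9 and 1 adjusted over the list alone), RRM2, a subunit of ribonucleotide reductase, by 0.50 ± 0.10, with an edgeR adjusted p of 0.00489, and 0.0895 in the 8 libraries alone (camera adjusted p = 0.00311; adjusted p = 0.286 with an estimated correlation). Of 27 proteasome genes 1 fell and 0 rose (1 and 0 adjusted over the list alone), with camera adjusted p = 0.00131 and adjusted p = 0.194 with an estimated correlation.

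The calls of 3 more lists against WT were lost when single libraries were left out. Immediate early genes had 6 of 23 fallen and 0 risen in R117fs (9 and 0 adjusted over the list alone), EGR1 among them, with camera adjusted p = 0.00131 and adjusted p = 0.535 with an estimated correlation; it was 0.0856 without R117fs replicate 1 and 0.0574 by fry. Integrated stress response genes had 3 of 21 fallen and 0 risen (4 and 0 adjusted over the list alone), with camera adjusted p = 0.0225 and adjusted p = 0.73 with an estimated correlation; it was 0.0681 without WT replicate 1, 0.0924 without R117fs replicate 2, 0.281 without R117fs replicate 3 and 0.182 by fry. YAP/TAZ targets had 3 of 16 fallen and 0 risen (4 and 0 adjusted over the list alone), ANKRD1 by 1.48 ± 0.21, with camera adjusted p = 0.0336 and adjusted p = 0.194 with an estimated correlation. It was 0.0513 without WT replicate 2, 0.0504 without R117fs replicate 1, 0.09 without R117fs replicate 2 and 0.0564 without R117fs replicate 3. The other 13 lists did not pass, with camera adjusted p from 0.11 to 0.917: 2 of 18 p53 targets rose and 0 fell (2 and 1 adjusted over the list alone; 0.49), and 0 of 17 Wnt/beta-catenin targets changed (0.496). Glycolysis passed without R117fs replicate 4 (0.00163) and with the GC trend removed (0.00203), and fry gave hypoxia 0.0373.

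G659fs was also compared with WT. ESRP1 fell by 1.74 ± 0.18 on the log2 scale (4.33 ± 0.71 CPM in WT and 1.31 ± 0.25 in G659fs; SD, n = 4), DHRS2 by 1.60 ± 0.28, NECTIN4 (chromosome 1, 161070995 to 161089599) by 1.58 ± 0.14 and TCEAL7 by 1.17 ± 0.14. KREMEN2, a receptor for Dickkopf proteins, rose 1.82-fold and the amino acid transporter gene SLC7A7 1.80-fold. Fibronectin, FN1, rose by 0.48 ± 0.08. Their edgeR adjusted p ran from 1.8e-05 for NECTIN4 to 0.0085 for DHRS2. In all 953 genes changed (5.677%), the fewest of the 6 comparisons in the reported fit of all 16 libraries. That rank did not hold without R117fs replicate 4 (3530, against 1617 for R117fs and WT), with the GC trend removed or in the 8 libraries alone. Of the 953 genes 390 were higher and 563 lower, and 74 changed at least 2-fold, 11 higher and 63 lower. This count depended on single libraries: it was 150, 211 and 372 without WT replicates 1, 3 and 4, and 100, 116 and 371 without G659fs replicates 2, 3 and 4. It was 601 without a low-count filter, 438 with the effective length offset, 1663 with DESeq2, 4660 with the 8 libraries alone and 3059 with the GC trend removed. Of 55 genes that the naming rule took here, 43 lost their call without some single library, and the genes named in this paragraph are from the 10 whose call held throughout.

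Proteasome genes were lower in G659fs than in WT, 3 of 27 fallen and 0 risen (8 and 0 adjusted over the list alone; camera adjusted p = 4.8e-05; adjusted p = 0.193 with an estimated correlation). Integrated stress response genes fell in 3 of 21 cases and rose in 0 (7 and 0 adjusted over the list alone), with camera adjusted p = 8.8e-05, 0.0575 by fry, and adjusted p = 0.389 with an estimated correlation. Unfolded protein response genes fell in 4 of 20 cases and rose in 0 (8 and 0 adjusted over the list alone), the transcription factor XBP1 by 0.35 ± 0.07, with camera adjusted p = 0.00026, 0.0765 by fry, and adjusted p = 0.389 with an estimated correlation. Targets of p53 fell in 4 of 18 cases and rose in 0 (5 and 0 adjusted over the list alone); PHLDA3 fell by 0.59 ± 0.12 (edgeR adjusted p = 0.0117), which became 0.0506 without WT replicate 1, 0.0583 without G659fs replicate 2 and 0.0616 without G659fs replicate 3. Camera gave that list adjusted p = 0.00171 and adjusted p = 0.193 with an estimated correlation. DNA replication genes fell in 1 of 20 cases and rose in 0 (1 and 0 adjusted over the list alone), with camera adjusted p = 0.0428 and adjusted p = 0.389 with an estimated correlation. That call was lost without GFP replicate 1 (0.0524), WT replicate 1 (0.0879), WT replicate 4 (0.053) or G659fs replicates 2, 3 or 4 (0.0679, 0.0575 and 0.0733), and fry gave 0.0765.

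Higher lists in G659fs against WT held few genes past the threshold. TGF-beta and BMP targets rose in 3 of 17 cases and fell in 0 (5 and 0 adjusted over the list alone), FN1 and SMAD6, the latter by 0.57 ± 0.10 with an edgeR adjusted p of 0.00593, and 0.0654 under the effective length offset (camera adjusted p = 0.000296; adjusted p = 0.264 with an estimated correlation). RAS/MAPK output rose in 2 of 20 genes and fell in 0 (5 and 0 adjusted over the list alone), with camera adjusted p = 0.000191, 0.11 by fry, and adjusted p = 0.389 with an estimated correlation. Immediate early genes rose in 1 of 23 cases and fell in 1 (3 and 1 adjusted over the list alone), with camera adjusted p = 0.000339, 0.117 by fry, and adjusted p = 0.389 with an estimated correlation. Wnt ligands and receptors rose in 2 of 28 cases and fell in 1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.00889; adjusted p = 0.193 with an estimated correlation). Wnt/beta-catenin targets had 1 of 17 risen and 1 fallen (2 and 1 adjusted over the list alone), with camera adjusted p = 0.0176 and adjusted p = 0.389 with an estimated correlation; it was 0.0582 without WT replicate 1, 0.0765 by fry and 0.0557 with the GC trend removed. Cholesterol synthesis genes rose in 1 of 22 cases and fell in 0 (1 and 0 adjusted over the list alone), with camera adjusted p = 0.0428 and adjusted p = 0.395 with an estimated correlation. That call was lost without WT replicates 1 or 3 (0.0925 and 0.0524), without G659fs replicates 2 or 3 (0.0779 and 0.0534), and fry gave 0.152.

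The other 12 lists did not pass in G659fs against WT, with camera adjusted p from 0.0549 to 0.916, and several lay close to the threshold. Mitochondrially encoded genes (0 of 13 changed, 0 adjusted over the list alone; 0.0549) passed without GFP replicates 2, 3 or 4 (0.0491, 0.0467 and 0.0399), WT replicates 1 or 3 (0.00156 and 0.0218) or G659fs replicates 1 or 4 (0.026 and 0.0254). Mitosis genes passed without WT replicate 1 (0.0258) or R117fs replicate 4 (0.0362). Of 8 fibroblast markers 3 rose and 0 fell (3 and 1 adjusted over the list alone; 0.0634), and that list passed without WT replicate 2 (0.0434) or G659fs replicate 1 (0.0397). TNF/NF-kappaB genes had 3 of 22 risen and 0 fallen (3 and 0 adjusted over the list alone; 0.0799), passing without WT replicate 2 (0.0434) or G659fs replicate 1 (0.0312). Among them NFKBIA rose by 0.44 ± 0.08 (edgeR adjusted p = 0.00798, and 0.077 with the effective length offset).

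The 2 frameshift variants were compared with each other last. ETV5 was 12.7-fold higher in G659fs than in R117fs (8.74 ± 1.00 against 0.716 ± 0.256 CPM; SD, n = 4), SPRY4 12.3-fold, EGR1 8.21-fold, CXCL8 19.2-fold and FOS 4.75-fold. CXCL8 (0.35 ± 0.22 CPM) and SPRY4 (0.18 ± 0.05 CPM) were near the floor in R117fs, so the size of their differences is uncertain. SLC22A31 was lower by 2.61 ± 0.24 on the log2 scale, DERL3 by 2.52 ± 0.20 and PDIA4 by 1.58 ± 0.15. Their edgeR adjusted p ran from 1.8e-07 for EGR1 to 0.00123 for FOS. In all 2412 genes changed (14.37%), 1066 higher and 1346 lower in G659fs, and 222 at least 2-fold, 83 higher and 139 lower. The count was 1390 without G659fs replicate 2, 1320 without G659fs replicate 3, 4012 without R117fs replicate 4 and 796 with the 8 libraries alone. With the GC trend removed it was 4691, 2383 higher and 2308 lower.

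Against R117fs, 17 of 20 unfolded protein response genes were lower in G659fs and 0 higher (17 and 0 adjusted over the list alone), HSPA5 by 1.40 ± 0.14, HYOU1 by 1.14 ± 0.11 and HERPUD1 by 0.89 ± 0.10 (camera adjusted p = 6.6e-14; adjusted p = 0.0943 with an estimated correlation). Targets of p53 fell in 5 of 18 cases and rose in 0 (5 and 0 adjusted over the list alone), with camera adjusted p = 0.0016 and adjusted p = 0.111 with an estimated correlation. PHLDA3 fell by 0.92 ± 0.12, AEN by 0.77 ± 0.12 and SPATA18 by 0.69 ± 0.09. RAS/MAPK output was higher in 10 of 20 genes and lower in 0 (16 and 0 adjusted over the list alone), with camera adjusted p = 2.1e-10 and adjusted p = 0.128 with an estimated correlation. ETV4 rose by 2.84 ± 0.32. Immediate early genes rose in 9 of 23 cases and fell in 0 (14 and 0 adjusted over the list alone), with camera adjusted p = 4.7e-08 and adjusted p = 0.156 with an estimated correlation. ARC rose by 1.28 ± 0.19, the phosphatase DUSP1 by 0.72 ± 0.12 and FOSB by 1.22 ± 0.21. TNF/NF-kappaB genes rose in 14 of 22 cases and fell in 2 (15 and 2 adjusted over the list alone), with camera adjusted p = 1.0e-06 and adjusted p = 0.0577 with an estimated correlation. NFKBIA rose by 0.95 ± 0.09 and the adhesion receptor ICAM1 by 1.04 ± 0.17. Heat shock genes rose in 9 of 16 cases and fell in 0 (10 and 0 adjusted over the list alone), with camera adjusted p = 4.7e-06 and adjusted p = 0.128 with an estimated correlation. HSPA8 rose by 0.73 ± 0.12 and DNAJB1 by 0.71 ± 0.12.

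Mitosis genes rose in 6 of 20 cases and fell in 0 in G659fs against R117fs (14 and 0 adjusted over the list alone), the proliferation marker MKI67 by 0.50 ± 0.10 and CENPF by 0.37 ± 0.09 (camera adjusted p = 2.7e-06; adjusted p = 0.246 with an estimated correlation). TGF-beta and BMP targets rose in 6 of 17 cases and fell in 0 (10 and 0 adjusted over the list alone), with camera adjusted p = 8.1e-05 and adjusted p = 0.128 with an estimated correlation. ID1 rose by 1.18 ± 0.20, ID2 by 0.64 ± 0.08 and SMAD6 by 0.73 ± 0.10. YAP/TAZ targets rose in 4 of 16 cases and fell in 0 (6 and 0 adjusted over the list alone), with camera adjusted p = 0.0016 and adjusted p = 0.0577 with an estimated correlation. ANKRD1 rose by 1.68 ± 0.21, CYR61 by 0.54 ± 0.09 and CTGF by 0.59 ± 0.10. Wnt/beta-catenin targets rose in 5 of 17 cases and fell in 0 (6 and 0 adjusted over the list alone), with camera adjusted p = 0.014 and adjusted p = 0.301 with an estimated correlation. DKK1 rose by 1.16 ± 0.22 and FZD7 by 0.33 ± 0.07. Wnt ligands and receptors rose in 6 of 28 cases and fell in 2 (7 and 2 adjusted over the list alone), FZD9 by 0.69 ± 0.10 and FZD1 by 0.51 ± 0.08, with camera adjusted p = 0.0197 and adjusted p = 0.128 with an estimated correlation. That call was lost without R117fs replicate 2 (0.0558) or R117fs replicate 3 (0.0739). Mitochondrially encoded genes had 0 of 13 changed (0 adjusted over the list alone), with camera adjusted p = 0.0294 and adjusted p = 0.629 with an estimated correlation; it was 0.092 without R117fs replicate 1, 0.0898 without R117fs replicate 2, 0.105 without G659fs replicate 2, 0.0705 without G659fs replicate 3, 0.136 by fry and 0.209 with the GC trend removed. The other 11 lists did not pass, with camera adjusted p from 0.15 to 0.949. Of these, DNA replication passed without R117fs replicate 1 (0.0491), glycolysis without R117fs replicate 4 (0.0128) and with the GC trend removed (0.0284), and fry gave hypoxia 0.0179.

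**Figure D3:**
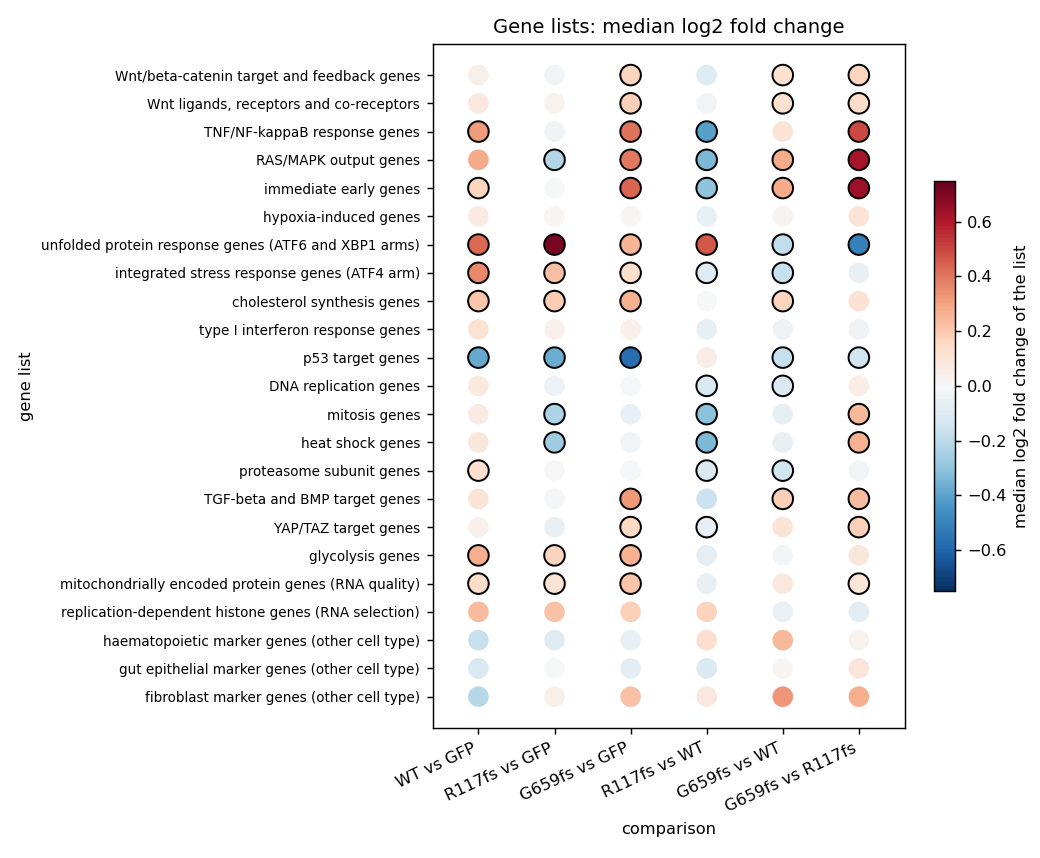
Median log2 fold change of the 23 gene lists in the 6 comparisons, coloured by its size and direction, with a black ring where camera passed at its preset correlation. Unfolded protein response genes are highest in R117fs against GFP (0.71), and p53 targets are lowest in G659fs against GFP (-0.57).

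**Figure D4:**
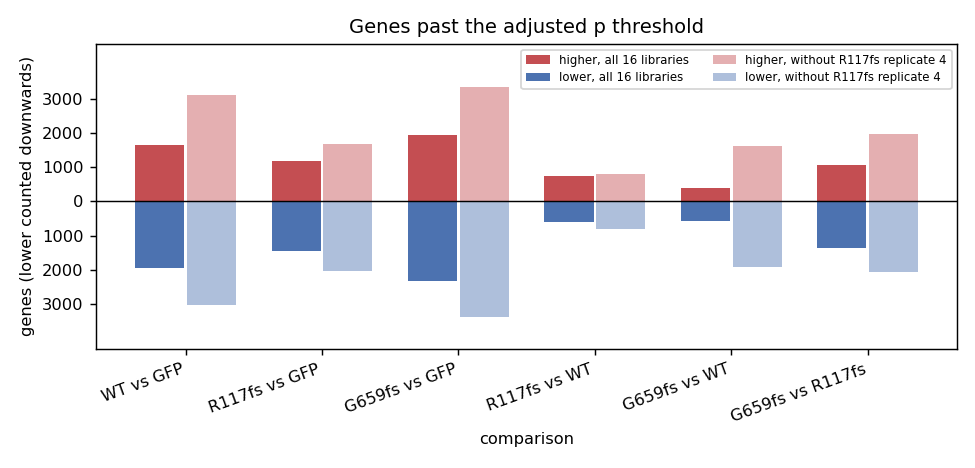
Number of genes past the threshold in each comparison, higher and lower, with all 16 libraries and without R117fs replicate 4. The total runs from 953 to 4258 with all libraries and from 1617 to 6723 without that one.

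How far the constructs shared their changes against GFP was measured over 16786 genes without RNF43. The Pearson correlation of log2 fold changes, across genes, which are not independent replicates, was 0.738 for WT and G659fs, 0.599 for WT and R117fs and 0.572 for R117fs and G659fs. The jackknife standard errors over libraries were 0.095, 0.119 and 0.087, and differences between the pairs were not tested. Shared control libraries alone gave 0.503, 0.51 and 0.505 in simulations of unchanged groups, and the last 2 correlations lie within 1 standard error of these. By itself this does not show that nothing was shared. The covariances were 0.1278, 0.0937 and 0.092 against 0.031, 0.0323 and 0.0317 simulated, differences of 0.0968, 0.0613 and 0.0603. With the GFP libraries split 2 and 2, the correlations were 0.483, 0.357 and 0.341. No control library is then shared within a pair, and the lowest values over the splits were 0.439, 0.333 and 0.303. This argues against shared control libraries as the whole of the correlation. WT and G659fs raised 859 genes in common and lowered 1332, where independent lists would share 192 and 268 and split controls gave 268 and 649. WT and R117fs shared 580 higher and 880 lower (116 and 167 for independent lists; 156 and 354 with split controls), and R117fs and G659fs 511 and 916 (137 and 198; 102 and 380). The values for independent lists come from the list sizes with all controls. None is given for split controls, so those overlaps cannot be set against them. Calls in opposite directions, with all controls, numbered 5, 9 and 26 for WT and G659fs, WT and R117fs, and R117fs and G659fs. Changes common to the constructs cannot be told apart from a difference of the GFP cells themselves. Splitting the GFP libraries does not remove such a difference.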

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

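In this part the tests of low depth and of a mislabelled sample, and the use of the measured WT share against a full-length cDNA, were chosen only after the result was seen. Single libraries lay far from the other 3 of their group in 9 of 84 sets of 4 values (total counts, the RNF43 share and 19 genes, in 4 groups), by Dixon's test, where chance picks about 1 in 20. GFP replicate 3 had total counts of 30.94 in units of 1000000 (25.44 to 26.38 in the other 3). In R117fs replicate 1, PDIA4 was at 405.0 CPM (776 to 831), IL32 at 2.33 CPM (4.67 to 4.92) and SPRY4 at 0.10 CPM (0.205 to 0.213). In R117fs replicate 4, NFKBIA was at 26.3 CPM (20.7 to 21.4) and FTCD at 1.90 CPM (1.204 to 1.253). In WT replicate 1, ETV5 was at 3.10 CPM (5.80 to 6.26) and ALPK3 at 2.69 CPM (4.89 to 5.06), and PHLDA3 was at 16.4 CPM in WT replicate 2 (19.5 to 20). Counts outside the comparisons also differed: the retained-intron transcript of RNF43, ENST00000582293, had 6378, 18366, 15655 and 0 estimated counts in R117fs replicates 1 to 4, and at most 1.31 in GFP, 14.53 in WT and 10.56 in G659fs libraries. Reads simulated from the intact coding sequence, without introns, put 0.98% on this transcript at 50 bases and 0% at 75 and 100. Measured shares averaged 0.5006% in R117fs and 0.0005% in WT. The counts alone therefore do not show a retained intron. R117fs replicate 1 differed from replicates 2 and 3 by a chi-square per degree of freedom of 72.41 and 81.91, and by 17.13 and 16.44 without RNF43.

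R117fs replicate 4 stood apart from the other R117fs libraries, with an SD of deviations of 0.4845 that followed GC content (Spearman 0.883). GC content was weighed first: with the trend removed the SD was 0.2942, still above the highest of the other 15 libraries treated alike (0.2388), so GC content argues for part of the deviation and against being the whole of it. Low depth was weighed next: replicate 3, of nearly the same depth, had deviations 1.81 times smaller, which argues against it. A mislabelled library was tested by its RNF43 reads, of which 0.0048% fell on ENST00000577625 (95% interval 0.00371% to 0.00613%, counting error), against about 72% in WT and G659fs libraries, while RNF43 was at 69368 CPM in it (30191 to 94568 in the other 3), which argues against a WT, G659fs or GFP library. It also had 0 counts on ENST00000582293, unlike the other 3 (6378 to 18366), so a library from outside these groups stays open. An earlier form of that test decided nothing and was replaced after its result was seen: of 474 genes that separate the other 3 R117fs libraries from the other groups, 64.3% lay on the R117fs side in replicate 4. With replicates 1, 2 and 3 held out in turn it was 22.3% of 921 genes, 70.7% of 413 and 63.8% of 461. Differences in library preparation or culture stay open and were not tested.

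RNF43 reads of R117fs fell on other annotated transcripts than those of WT, and 2 forms of the construct were weighed. The coding sequence has 2352 bases and 783 codons, and a frame shifted at codon 117 meets a stop after 156 codons. Reads of 75 bases simulated from a cDNA that ends there gave 0% on ENST00000577625, against 0.0032% ± 0.0014 measured in R117fs (SD, n = 4), so a shortened cDNA may account for the pattern. A full-length cDNA with 1 base deleted gave 78.51%, past the bound set before the test. The simulation assumes a read length, even coverage and no vector sequence, but the WT libraries, made alike, measured 72.5% ± 0.42, which argues against that form. The end of the cDNA, and an RNA shortened in the cells, stay open and were not tested. No biological explanation was tested.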

How the results depend on the processing

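In this part the removal of each library's GC trend was chosen only after the result was seen. Of 439 results for named genes, 438 kept their direction and side of the threshold with RLE size factors, 438 with RNF43 counts removed before normalization, 428 with the legacy fit, 429 with limma-voom, 433 of 438 with DESeq2, 423 of 424 with the stricter filter, 389 without a filter and 435 with the GC trend removed. The effective length offset kept 346, lost 90 and reversed 3, all PGK1: 1.48 in WT, 1.18 in R117fs and 1.49 in G659fs against GFP, where the reported values are -0.87, -1.10 and -0.84. That offset also turned the RNF43 difference of R117fs against WT from 0.36 to -0.289, neither past the threshold (edgeR adjusted p = 0.543 and 0.69). The offset scales counts by the effective length of a gene's transcripts, so counts moving between long and short transcripts move the fold change. For PGK1 a transcript of 4887 bases held 96.9% of counts in GFP and about 51% in the RNF43 groups. Its other transcripts had 307 to 960 bases. For RNF43 the transcript of 2198 bases held 72.5% in WT, and that of 4367 bases 99.4% in R117fs. Whether these shares are right, and whether annotated lengths hold for the RNF43 constructs, was not tested. A fit of only the 8 libraries of a comparison kept 345 of 437. Leaving out 1 library kept from 356 (G659fs replicate 2) to 424 (R117fs replicate 1). The median log2 fold change of all genes stayed between -0.009 and 0.007 under every scaling tried. Each of these scalings assumes that most genes do not change, so a shift common to all genes would not show.

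Counts of changed genes, in the order WT, R117fs and G659fs against GFP, R117fs and G659fs against WT and G659fs against R117fs, were 5919, 588, 6993, 154, 4660 and 796 with only the 8 libraries, and 6074, 4433, 6556, 2866, 3059 and 4691 with the GC trend removed. With the effective length offset R117fs against GFP gave 1740, R117fs against WT 853 and G659fs against WT 438. G659fs against WT also gave 601 without a filter and 1663 with DESeq2. In the 8 libraries alone, comparisons without R117fs gave more genes than reported and those with it fewer. All groups share 1 estimate of the spread in the reported fit, so a library outside a comparison can move its count. Without R117fs replicate 4, G659fs against WT gave 3530 and WT against GFP 6133. How much of each change this accounts for was not tested. Lists called with an estimated correlation numbered 1, 2, 1, 0, 0 and 0 (9, 9, 13, 10, 11 and 12 reported), and fry, which tests against no change, gave 4 for G659fs against WT. The cause was not tested. With the GFP libraries split 2 and 2, the correlations fell to 0.357 (WT and R117fs), 0.483 (WT and G659fs) and 0.341 (R117fs and G659fs), since no control library is then shared and each fold has fewer.

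With each library left out in turn the counts ran from 2222 to 6133, 1455 to 3701, 3067 to 6723, 626 to 2607, 100 to 3530 and 1320 to 4012 in the same order. The extremes came without GFP replicate 4 (2222, 1455 and 3067), R117fs replicate 4 (6133, 3701, 6723, 3530 and 4012), WT replicate 2 (626), R117fs replicate 1 (2607), G659fs replicate 2 (100) and G659fs replicate 3 (1320). Others past 1.5 times were GFP replicate 2 (1718 for R117fs against GFP), WT replicates 1, 3 and 4 (779, 696 and 660 for R117fs against WT; 150, 211 and 372 for G659fs against WT), G659fs replicates 3 and 4 (116 and 371 for G659fs against WT) and G659fs replicate 2 (1390 for G659fs against R117fs). The cause was not tested. Over all alternatives, lists that did not pass changed direction in 75 cases, with adjusted p of at least 0.496. Lists called numbered 8 to 11, 7 to 9, 11 to 13, 8 to 11, 9 to 14 and 10 to 13. The RNF43 difference ran from 10.47 to 11.04, 10.84 to 11.41, 10.04 to 10.61, 0.16 to 0.62, -0.54 to -0.38 and -1.05 to -0.60, the last passing the threshold without R117fs replicate 1 (-1.05, edgeR adjusted p = 0.0276). The correlations ran from 0.507 to 0.65 (WT and R117fs), 0.668 to 0.764 (WT and G659fs) and 0.525 to 0.619 (R117fs and G659fs).

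Whether the replicate numbers pair the libraries was not settled. Of 24 pairs of groups and numbers, 4 correlated above 0.1 (range -0.062 to 0.16) and 9 were best with their own number. With the replicate block the counts were 3940, 2901, 4564, 1841, 1343 and 2737, each above the reported count. The block kept 436 of 439 named results. The block ended 1 list call, the integrated stress response in G659fs against GFP (adjusted p = 0.0582).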

Other observations

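In this part the test of R117fs replicate 4 alone was chosen only after the result was seen. Unfolded protein response genes were higher in R117fs than in GFP, with a median log2 fold change of 0.71 over 20 genes, 19 of them past the threshold. The mean log2 CPM of the list was 7.362 in R117fs replicate 1 and 7.706 to 7.823 in the other 3, against 6.76 to 6.879 in GFP. Without R117fs replicate 4 the median was 0.73, which argues against that library as the cause. Of 10000 random lists matched on GC content, gene length and expression, 100% had a lower median, which argues against a bias of GC content or length. The amount of overexpressed RNA and a difference between cultures stay open and were not tested.

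Whether other groupings of the libraries give as many genes was tested over the 35 splits of the 8 libraries of each comparison, the real one included. In each comparison only the real split reached the reported count, and 1 of 35 is the smallest share this test can reach. The other splits mix the groups, which widens the spread within each, so low counts are expected there. A difference between cultures or batches would pass this test as well. Chance and such differences are therefore not excluded. WT against GFP gave 3603 genes and at most 1 in another split, G659fs against GFP 4258 and at most 1, R117fs against WT 1362 and at most 2, and G659fs against WT 953 and at most 0. For R117fs against GFP the values were 2620 and 387, the latter with GFP replicates 1, 2 and 4 set together with R117fs replicate 4. For G659fs against R117fs they were 2412 and 41.

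PGK1 counts were divided between its annotated transcripts differently in GFP: ENST00000373316 held 96.9% ± 1.68 of them in GFP, 51.2% in WT, 51.4% in R117fs and 51.2% in G659fs (SD, n = 4). Since all RNF43 groups share this pattern, it may come from a difference of the GFP cells or their construct, which was not tested. ENST00000584437, an RNF43 transcript, had 160.5 to 184.3 counts in the 4 GFP libraries.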
